A study of Mus musculus with 18 samples.

How the data were processed

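The series measured kidney messenger RNA on Affymetrix mouse expression arrays, 3 days after unilateral ureteral obstruction (UUO) or a sham operation. UUO is a surgical model in which 1 ureter is tied off, so that the kidney behind it is obstructed. Per the labels, the mice were wild type (WT) or lacked TIMP2 or TIMP3, 2 of the tissue inhibitors of metalloproteinases, on a C57BL/6 background. The right ureter was ligated, and the kidney of the operated side was frozen and used for total RNA with an integrity number above 7. Each of the 6 groups (WT, TIMP2-/- and TIMP3-/-, each with sham and UUO) held 3 arrays, 18 in all, and the labels describe the samples as biological replicates. An array is named here by its group and the replicate number of its label, such as WT UUO 2.

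The deposited values were on a linear intensity scale, 1 value per probe set and array, and RMA (robust multi-array average, which corrects background, normalizes by quantiles and summarizes probes) is credited by the submitters' processing notes; its version is not given in the sources used here. RMA output is usually on a log2 scale, and the step that led to linear values is not given in the sources used here. Each array's median intensity lay between 201 and 247. Because quantile normalization sets the arrays' distributions nearly equal, a shift of all transcripts in 1 direction cannot be seen in these values. Sequencing depth does not apply to arrays, and it is the number of arrays per group, 3, that limits the precision. Values were converted to log2 with no pseudocount, and none was missing.

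Of 22690 probe sets, 64 were control probe sets and were left out. Among the other 22626, 20380 were paired with 1 gene symbol by the platform annotation, 691 with several and 1555 with none; a probe set with several symbols or none named no gene. A total of 4956 genes had several probe sets, and the probe set with the highest mean over all arrays then stood for the gene, which left 12393 genes. Of these, 12369 were matched to the RefSeq gene table of assembly GRCm38.p6, which changed no symbol. No genome build is named by the sources used here for the values, so the RefSeq table served only for names and for which genes lie near each other, and no coordinates are given.

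Tests used limma 3.58.1 in R 4.3.3. One linear model with 6 group means was fitted to the log2 values of the 18 arrays, with 12 residual degrees of freedom and 3.35 prior degrees of freedom from the empirical Bayes step, so that all groups shared 1 estimate of each gene's spread. The median residual SD was 0.222 on the log2 scale. The comparisons numbered 11: UUO against sham in each genotype, the genotypes against each other after UUO, each knockout against WT after sham, and the 3 differences between genotypes of the UUO response. P-values were adjusted with the Benjamini-Hochberg method within each comparison, and a gene passed at an adjusted p under 0.05. Log2 fold changes are given with the standard error (SE) of the fit, and intensities as mean ± SD of n = 3 arrays. An exact 2-sided permutation test of 3 arrays against 3 cannot give a p below 0.1, so single genes rest on the model's pooled spread.

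Gene lists for the tissue and the operation numbered 32 and held 476 distinct genes. They covered the TIMP family, matrix metalloproteinases, ADAM and ADAMTS proteases, interstitial matrix, basement membrane, fibroblast and myofibroblast markers, the TGF-β pathway and its targets, tubular injury, proximal tubule, and the loop, distal tubule and collecting duct. Others covered podocyte, endothelial, macrophage and monocyte, lymphocyte and NK, and neutrophil markers, chemokines and cytokines, the TNF and NF-κB pathway, interferon-induced genes, complement, apoptosis, cell cycle, fatty acid oxidation, oxidative phosphorylation, EGF receptor ligands and receptors, epithelial-mesenchymal transition regulators and immediate early genes. Markers of tissue that a kidney sample could carry with it were red cell, adrenal cortex, adipocyte, urothelium and skeletal muscle transcripts, and sex-linked genes were a check of the samples. Each list was tested with fry from limma, which asks whether its genes move on balance in 1 direction, apart from other genes. P-values were adjusted over the 32 lists of a comparison. The camera test asks another question, as it sets a list against all other genes, with an estimated correlation between genes. Each list p given with an estimated correlation is that of camera, not of fry. Counts of list members that passed are adjusted over all genes, and where stated over the list alone.

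Genes were named by rule. Timp2 and Timp3 were named in every comparison, as were Timp1, Mmp2, Mmp9, Tnf, Tgfb1, Col1a1, Acta2, Havcr1 and Lcn2. For each comparison the 8 largest rises and 8 largest falls among genes that passed were taken, in comparisons of 2 groups only where the replicate values of the groups did not overlap. From each list discussed, the 4 measured members with the smallest p were taken, of which 2 to 4 are printed, and all genes were named where a comparison called 5 or fewer. The groups, the comparisons, the tests, the 32 lists, the naming rule and most of the alternative settings were set before the data were examined. The choice of which lists to discuss, a list of 18 hepatocyte markers, the 3 arrays that were left out as doubted (WT UUO 2, WT sham 3 and TIMP3-/- UUO 2) and a replicate block for 2 comparisons on their own arrays were chosen after the data were seen.

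The labels number the replicates of every group alike, and whether equal numbers pair the arrays was checked from the correlation across genes of their deviations from the group means. For UUO against sham in TIMP2-/- the correlations of the pairs were 0.33, 0.32 and 0.57, and for TIMP2-/- UUO against WT UUO 0.21, 0.26 and 0.45, all above the limit of 0.1 set for pairing. In the former 1 of the 3 arrays checked correlated best with its own number, and in the latter all 3 did. The reported fits nevertheless held no pairs. In these 2 comparisons only, the alternative settings with a replicate block were read as a check of possible pairing, on the evidence of the data and not of the labels. Each of the other comparisons had at least 1 pair at or below that limit.

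The tests were first run on simulated data in which a set of genes was changed by known amounts. Simulated on UUO against sham in WT over 12393 genes, the test called 9 of 67 genes changed by 0.5 on the log2 scale (13.4%), 40 of 67 changed by 1 (59.7%) and 60 of 66 changed by 2 (90.9%), together with 5 genes that had not been changed. A list of 20 changed genes gave a fry p of 1.88e-12 and an unchanged list 0.595. The simulated genes varied independently, each with 1 spread for all groups. In the real arrays 46.5% of the variance within groups lay on 1 component. The median SD of a gene ran from 0.143 in TIMP2-/- sham to 0.264 in TIMP3-/- UUO. The simulated rates and list p therefore check the procedure and do not carry over to the real arrays. Alternative settings were the mean of a gene's probe sets, leaving out probe sets with the suffix of cross-hybridizing designs, testing every probe set, leaving out the dimmest 25% of genes, a variance trend with robust estimation, array weights, cyclic loess between arrays, a fit to only the arrays compared, a replicate block, a 2-fold minimum, and leaving out each array in turn.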

Results

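The data were 18 kidney expression profiles from WT, TIMP2-/- and TIMP3-/- mice, 3 arrays for each genotype after a sham operation and 3 after 3 days of UUO. The first principal component carried 67.2% of the variance and separated every UUO array (-89.7 to -6.1) from every sham array (27 to 58.7). The second carried 15.5%, and on it WT sham 3 (-60) and TIMP3-/- UUO 2 (-40.7) stood apart from the other arrays (-22.3 to 33.3). Correlations between replicates across genes ran from 0.955 to 0.975 in TIMP3-/- UUO and from 0.956 to 0.989 in WT UUO, and from 0.981 upward in the other 4 groups. Alb, the albumin gene of hepatocytes, had an intensity of 28106 on WT UUO 2, against 73 and 254 on the other WT UUO arrays. On the mean score of 18 hepatocyte markers, WT UUO 2 stood at 5.13 and no other array above 0.31. WT UUO 2, WT sham 3 and TIMP3-/- UUO 2 are called the 3 doubted arrays here.

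The targeted genes followed the genotype labels, Timp2 less clearly after sham than after UUO. Timp3, which encodes an inhibitor of metalloproteinases that binds to the extracellular matrix, had an intensity of 7500 ± 1436 in WT sham and 4863 ± 533.8 in WT UUO, but 49.22 ± 10.18 in TIMP3-/- sham and 36.94 ± 3.103 in TIMP3-/- UUO (SD, n = 3). Timp2, which encodes an inhibitor that also takes part in the activation of MMP2, had 1179 ± 263.4 in WT sham and 4138 ± 586.8 in WT UUO. In TIMP2-/- kidneys it had 639.8 ± 60.1 after sham and 823.9 ± 77.79 after UUO, so a signal remained. Of the 6 probe sets for Timp2, 5 were lower in TIMP2-/- UUO than in WT UUO, and the other was dim in every group (means 25.68 to 40.46). After sham none of the 6 passed between TIMP2-/- and WT with every probe set tested (limma, adjusted p 0.143 to 0.724). The brightest did not overlap there (570.8 to 680.9 against 970.6 to 1475), but another did (543.6 to 661.5 against 545.5 to 819.3). The labels of the TIMP2-/- sham arrays are thus only weakly checked. All 4 probe sets for Timp3 lay between 20.1 and 60.8 in TIMP3-/-. The 25th percentile of intensity was 56.8 to 64.2 on the 18 arrays, so Timp3 in both TIMP3-/- groups was near background, and its differences from the other genotypes below are lower bounds in size. A change with a group mean log2 below that of 56.8 is inexact in size. Among these with UUO were Sprr2f in each genotype, and Adipoq, Cd44, Mmp3, Cxcl1, Birc5 and Cidec in WT. In TIMP2-/- they were Cd44 and Ces1g, and in TIMP3-/- Postn, Cyp2d12, Snai2, Twist1 and Hba-a1. Others were BC018473, and Cfap97, Gsap, Mx1 and Dpys between TIMP3-/- UUO and WT UUO, and Dclk1 and Aspn between the obstructed knockouts. Their order among the largest changes is not exact. Where the probe sets lie relative to the deleted part of either gene is not given in the sources used here.

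**Figure D1:**
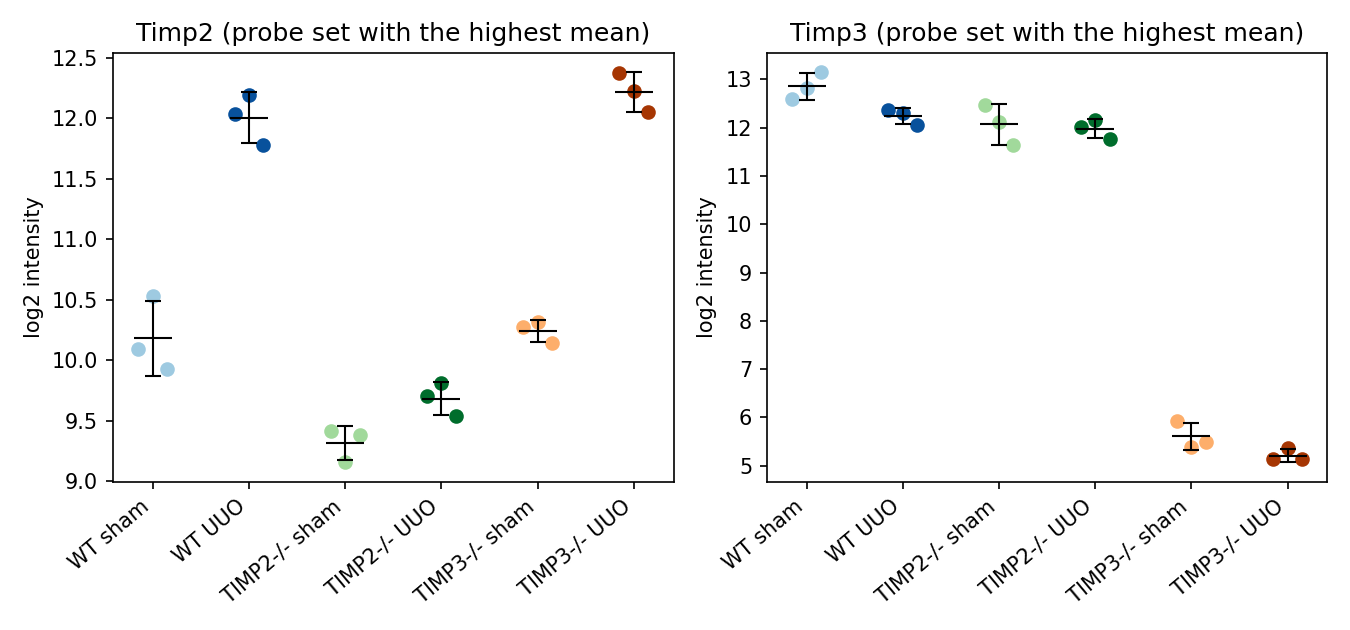
Log2 intensity of the probe set with the highest mean for Timp2 (left) and Timp3 (right), with a point for each of the 18 arrays and a line and bars for the mean ± SD of each group (n = 3). In intensity, Timp3 was at 49.22 or below on average in both TIMP3-/- groups, and Timp2 averaged 823.9 in TIMP2-/- UUO against 4138 in WT UUO.

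UUO against sham in WT asks what 3 days of obstruction do to the normal kidney. Tubular injury genes rose and tubular function genes fell. Havcr1 (KIM-1, a receptor that injured proximal tubule cells display) rose by 5.44 ± 0.21 on the log2 scale (limma, adjusted p = 4.4e-10), from an intensity of 143.9 to 6437. Lcn2 (NGAL, a secreted iron-binding protein of injured tubules) rose by 5.99 ± 0.34 (adjusted p = 2.15e-08). All 18 measured injury markers rose, with a median of 2.25, and among them were the adhesion molecules Vcam1 (4.07 ± 0.25) and Cd44 (4.68 ± 0.31). In all, 4086 of 12393 genes passed, 2078 higher and 2008 lower. The other large rises were Hp (5.91 ± 0.82), Sprr2f (5.70 ± 0.54), Adipoq (5.68 ± 1.21, dim in sham), Timp1 (5.60 ± 0.52), Col1a1 (5.17 ± 0.38) and Serpina10 (5.16 ± 0.27). The largest falls were those of Pvalb (-3.86 ± 0.28), Slc22a7 (-3.59 ± 0.58), Slc22a22 (-3.44 ± 0.45), Cyp2d12 (-3.41 ± 0.66), Egf (-3.39 ± 0.59), Hsd3b2 (-3.31 ± 0.59), Calb1 (-3.21 ± 0.50) and Slc22a30 (-3.03 ± 0.35), of which Egf, Pvalb and Calb1 are transcripts of the distal nephron and the Slc22 genes encode organic ion transporters. Of 21 proximal tubule markers, 20 fell (median -1.48; fry adjusted p = 0.000305, 0.204 with an estimated correlation), for example Lrp2 (-1.90 ± 0.25) and Cubn (-1.86 ± 0.25), the endocytic receptors of the proximal tubule, and Gatm (-2.25 ± 0.33). Of 19 loop, distal tubule and collecting duct markers, 9 fell and none rose (median -0.78; fry adjusted p = 0.00484, 0.328 with an estimated correlation), among them the anion exchanger gene Slc26a4 (-1.49 ± 0.29); without WT UUO 2 the median was -0.49 with 7 lower (0.0228). The injury list passed with fry (adjusted p = 1.36e-08) and with camera (0.0251). Without WT UUO 2 the count of genes was 2735 and the fall of Egf -2.41, and without the 3 doubted arrays the count was 2441.

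Genes of the extracellular matrix and of the cells that make it rose together in WT UUO. Of 22 interstitial matrix genes, 21 rose (median 3.13), including the fibrillar collagens Col1a1, Col3a1 (4.31 ± 0.22; limma, adjusted p = 9.82e-09) and Col1a2 (3.38 ± 0.22) and the proteoglycan Bgn (2.09 ± 0.14). Of 21 basement membrane genes, 13 rose and 3 fell (median 0.97, and 0.64 without the 3 doubted arrays), with Col4a1 at 1.91 ± 0.12 and Col4a2 at 1.95 ± 0.14. Of 14 fibroblast and myofibroblast markers, 10 rose (median 1.95), including Tagln (2.82 ± 0.26) and Pdgfrb (2.12 ± 0.21). Acta2, smooth muscle actin, rose by 2.66 ± 0.30 (adjusted p = 1.15e-05) with its brightest probe set, whose suffix marks a possible match to several transcripts; its other probe set, at -0.21, is dim (mean log2 5.48 against 12.27). In the TGF-β list 8 of 16 rose and 2 fell (median 1.10), with Tgfb1 at 1.43 ± 0.25, Tgfbr2 at 1.45 ± 0.18 and the target Ccn2 at 1.90 ± 0.27. Basement membrane passed with fry (adjusted p = 1.51e-08) and with camera (0.0251). The other 3 lists passed with fry only, interstitial matrix with 3.83e-06, fibroblasts with 1.56e-05 and TGF-β with 7.23e-06. Their camera adjusted p were 0.098, 0.106 and 0.0882.

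The proteases and their inhibitors also moved in WT UUO. Of 16 matrix metalloproteinases, 7 rose and 2 fell (median 1.03; fry adjusted p = 0.00145, 0.278 with an estimated correlation). Without WT UUO 2, 6 were higher and 1 lower with a median of 0.33 (0.00821), and without the 3 doubted arrays the call was lost (0.0664). Mmp2, a gelatinase, rose by 3.88 ± 0.37 (limma, adjusted p = 1.86e-06) and Mmp14, the membrane-bound protease that activates it, by 3.52 ± 0.40, with Mmp3 at 3.23 ± 0.50. Mmp9 did not pass (1.44 ± 0.83, adjusted p = 0.198): its intensity was 1090 on WT UUO 2, and 114 and 104 on the other WT UUO arrays. Of 13 ADAM and ADAMTS genes, 7 rose (median 0.74; fry adjusted p = 0.00103, 0.204 with an estimated correlation; median 0.46 without WT UUO 2, 0.00241), with Adam12 at 2.39 ± 0.35 and Adamts1 at 2.36 ± 0.35. The 4 inhibitors diverged: Timp1 and Timp2 rose (Timp2 by 1.82 ± 0.16, adjusted p = 9.73e-07), Timp3 fell by 0.61 (-0.61 ± 0.21, adjusted p = 0.0325), and Timp4 was at -0.19 ± 0.13 (adjusted p = 0.301). As a list they gave a fry adjusted p of 1.56e-05 (0.278 with an estimated correlation). The call of Timp3 was lost without WT sham 2 (adjusted p = 0.0639), WT sham 3 (0.133), WT UUO 2 (0.0647) or WT UUO 3 (0.094), and without the 3 doubted arrays (0.188). With the mean of its 4 probe sets the fall was -0.88 (adjusted p = 8.69e-05), and the replicates of WT sham and WT UUO did not overlap with any of the 4.

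Immune genes rose in WT UUO, led by those of macrophages. All 20 macrophage and monocyte markers rose (median 3.20), including the lipopolysaccharide co-receptor Cd14 (3.11 ± 0.17), the lysozyme gene Lyz2 (3.89 ± 0.24) and the C1q genes C1qa (3.28 ± 0.23) and C1qb (3.40 ± 0.22). Of 24 chemokines and cytokines 16 rose (median 1.65), for example Cxcl1 (4.33 ± 0.30) and Ccl5 (2.75 ± 0.25). In the TNF and NF-κB list 12 of 16 rose and 1 fell (median 1.00), with Icam1 at 2.05 ± 0.18 and Relb at 2.21 ± 0.21, while Tnf itself was at 0.00 ± 0.13 (limma, adjusted p = 0.999). Of 17 interferon-induced genes 14 rose (median 1.12), such as Gbp2 (2.71 ± 0.22) and Psmb8 (2.24 ± 0.22). Of 10 complement genes 6 rose (median 1.64), among them C1ra (2.17 ± 0.19) and C3ar1 (2.60 ± 0.26). The fry adjusted p were 1.41e-07 for macrophages, 4.31e-06 for chemokines, 8.72e-07 for TNF, 2.89e-06 for interferon and 4.12e-06 for complement. The camera adjusted p were 0.0882 for the first 4 and 0.098 for complement.

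Proliferation genes rose and genes of mitochondrial energy metabolism fell in WT UUO. Of 19 cell cycle genes 15 rose (median 1.68), with Birc5 (survivin) at 3.17 ± 0.34 and the mitotic kinase gene Cdk1 at 2.36 ± 0.26. Of 14 immediate early genes 10 rose (median 1.79), with Atf3 at 2.12 ± 0.14 and Jun at 2.01 ± 0.21. Of 16 apoptosis genes 6 rose and 1 fell (median 0.19), with Mcl1 (0.95 ± 0.21) and Apaf1 (1.41 ± 0.32) higher and Bid (-0.85 ± 0.16) lower. Of 16 fatty acid oxidation genes 14 fell and 1 rose (median -0.84), including Ppara, the nuclear receptor that drives the pathway (-1.77 ± 0.24; limma, adjusted p = 6.36e-05), and Cpt1a (-0.71 ± 0.12). Of 21 oxidative phosphorylation genes 14 fell (median -0.49), including Ndufs1 (-1.54 ± 0.21) and Sdha (-0.85 ± 0.12). The fry adjusted p were 1.35e-05 for cell cycle, 7.43e-06 for immediate early genes, 0.000834 for apoptosis, 0.000212 for fatty acid oxidation and 0.000627 for oxidative phosphorylation. The camera adjusted p were 0.098, 0.098, 0.3, 0.204 and 0.278. Without WT UUO 2 the oxidative phosphorylation genes that fell numbered 6 and those of fatty acid oxidation 9, and without the 3 doubted arrays 7 oxidative phosphorylation genes fell and 3 apoptosis genes rose. Counts adjusted over the list alone equalled those over all genes in WT UUO except for interstitial matrix (22 higher), basement membrane (4 lower), fibroblasts (12 higher), TGF-β (9 higher), loop and distal tubule (11 lower), chemokines (18 higher), interferon (1 lower), complement (1 lower), cell cycle (16 higher), oxidative phosphorylation (19 lower) and the lists given with the other observations.

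Adipocyte transcripts rose with the same operation. Of 6 adipocyte markers 4 rose in WT UUO (median 1.70; fry adjusted p = 0.0118, 0.312 with an estimated correlation), with Adipoq (adiponectin) at 5.68 ± 1.21 (limma, adjusted p = 0.00225), Cidec at 2.99 ± 0.65, Fabp4 at 1.86 ± 0.61 (adjusted p = 0.0291) and Retn at 1.54 ± 0.52 (adjusted p = 0.0325). Adipoq had intensities of 933 to 6388 on the WT UUO arrays, 1652 to 2728 on the TIMP2-/- UUO arrays and 349 to 7461 on the TIMP3-/- UUO arrays, against 16 to 728 on the 9 sham arrays. Without WT UUO 2 the list had 2 genes higher and an adjusted p of 0.0579, and without the 3 doubted arrays the adjusted p was 0.051. The call of Fabp4 was lost without WT sham 1, WT sham 2, WT UUO 1 or WT UUO 2, and that of Retn without any 1 of the 6 arrays except WT UUO 3. The 18 hepatocyte markers had a median of 1.29 in WT UUO, with none called over all genes and a fry p of 0.245 without adjustment.

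**Figure D2:**
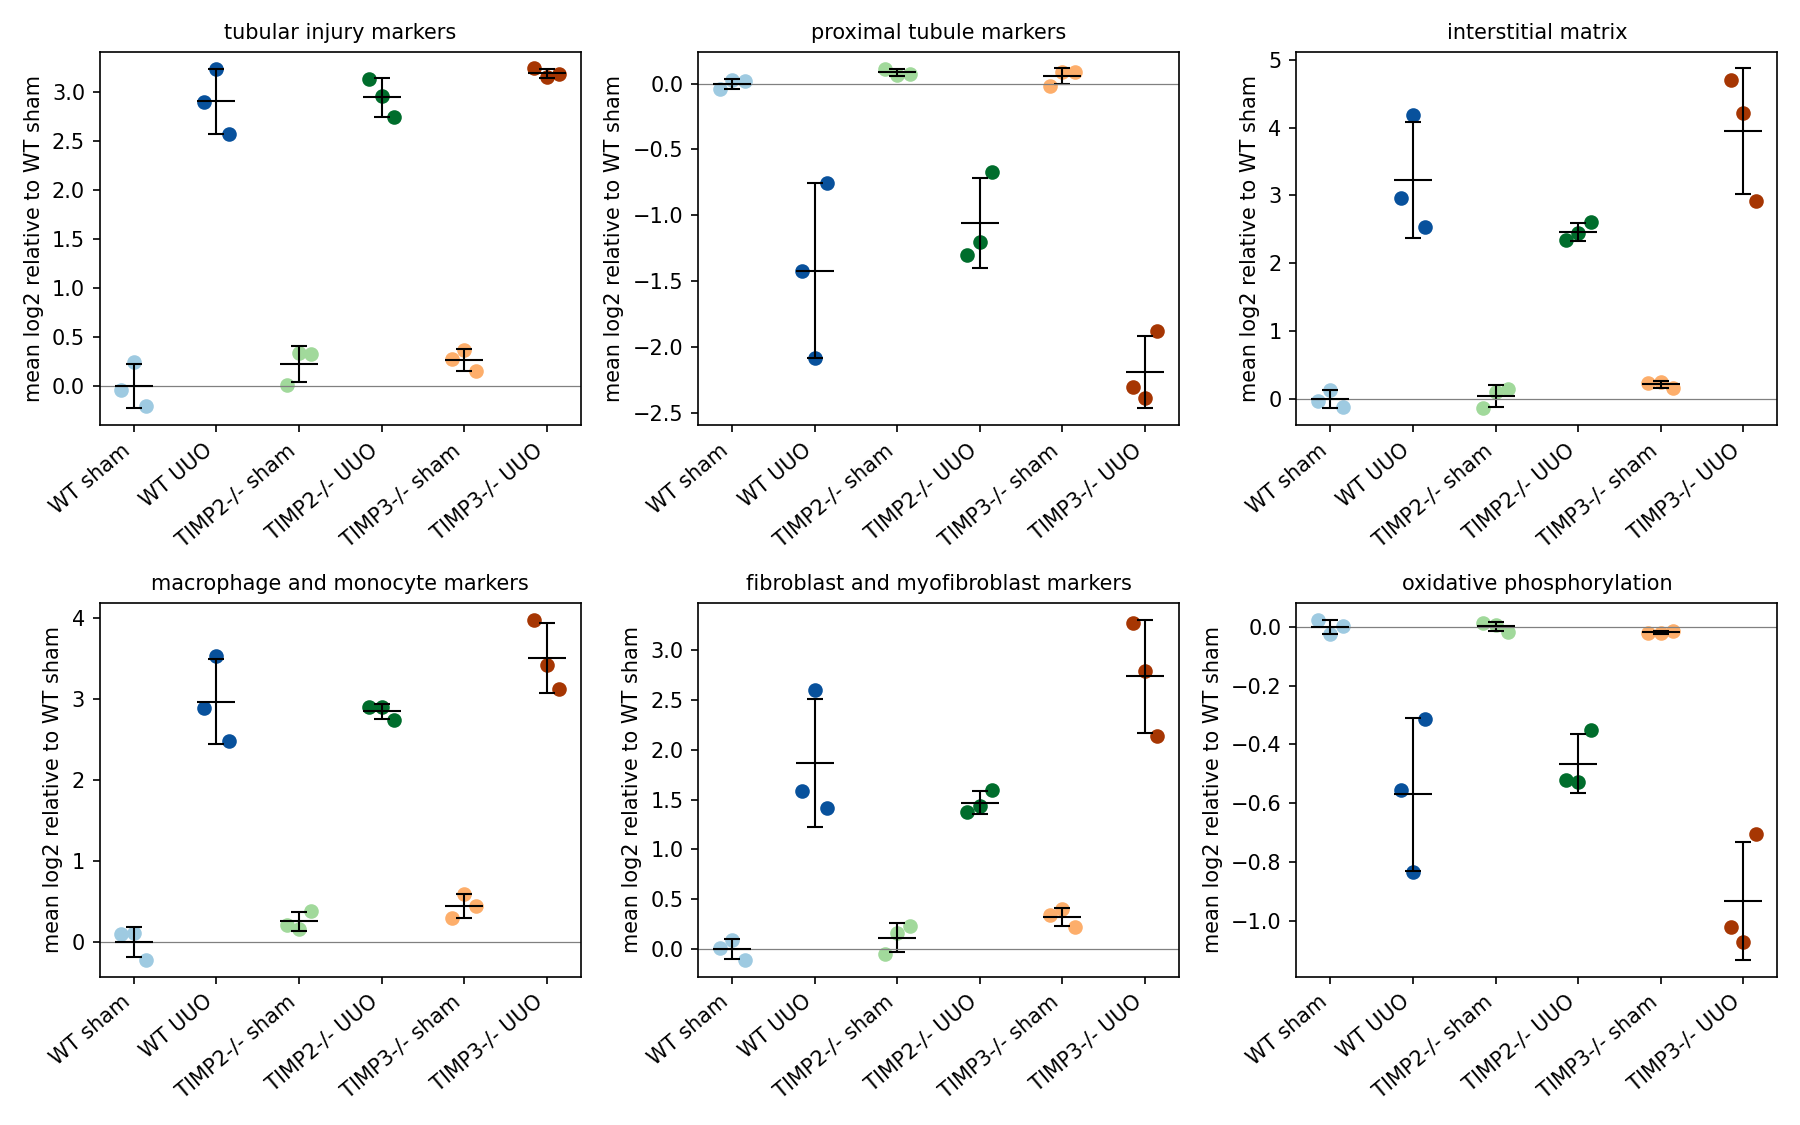
Mean log2 level of 6 gene lists relative to the mean of WT sham, with a point for each of the 18 arrays and a line and bars for the mean ± SD of each group (n = 3). Injury, matrix, macrophage and fibroblast levels were higher, and proximal tubule and oxidative phosphorylation levels lower, on every UUO array than on every sham array.

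**Figure D3:**
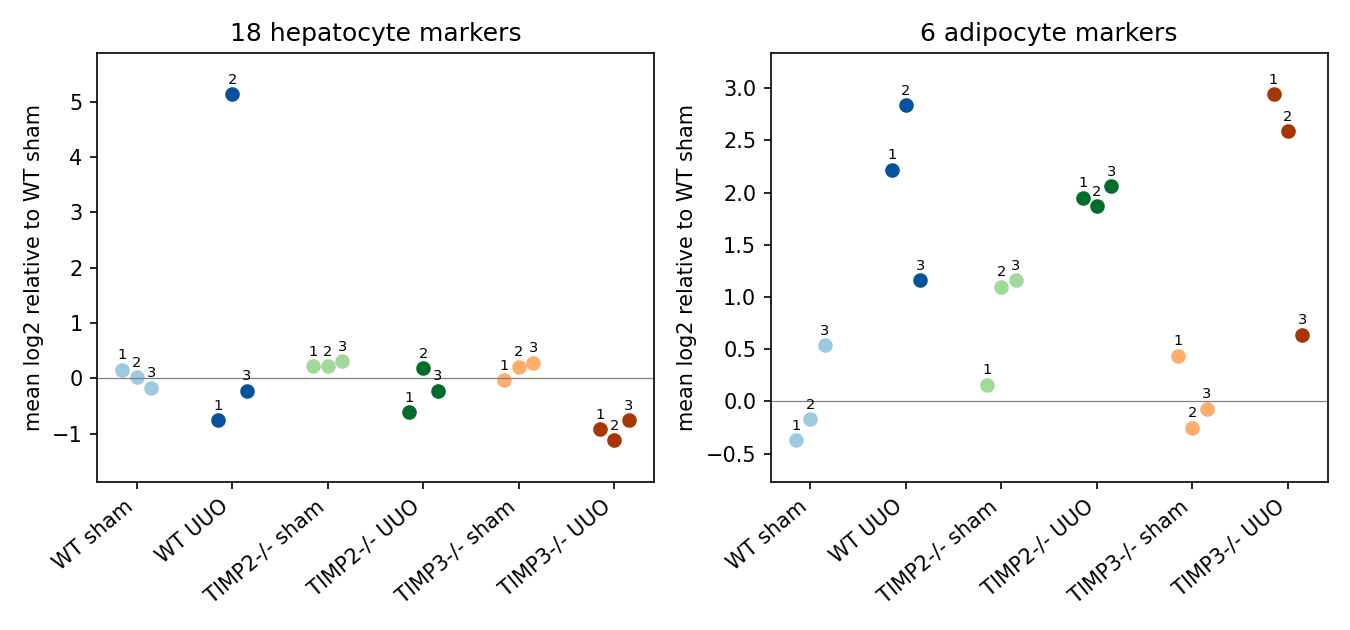
Mean log2 level of 18 hepatocyte and 6 adipocyte markers relative to the mean of WT sham, with a point and replicate number for each of the 18 arrays. The hepatocyte level was 5.13 on WT UUO 2 and at most 0.31 elsewhere; the adipocyte level was highest on TIMP3-/- UUO 1 (2.94), and on TIMP3-/- UUO 3 (0.64) it lay below that of TIMP2-/- sham 3 (1.16).

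UUO against sham in TIMP2-/- asks whether the kidney responds to obstruction without TIMP2. Injury, matrix and immune genes rose and genes of tubular function fell. Havcr1 rose by 6.29 ± 0.21 (limma, adjusted p = 4.93e-11) and Lcn2 by 5.68 ± 0.34, followed by Serpina10 (5.09 ± 0.27), Vcam1 (4.97 ± 0.25), Timp1 (4.91 ± 0.52), Cd44 (4.84 ± 0.31), Sprr2f (4.56 ± 0.54) and Ubd (4.55 ± 0.28). The largest falls were those of Ces1g (-3.88 ± 0.48), Pvalb (-3.84 ± 0.28), Cyp2d12 (-3.32 ± 0.66), Slc4a1 (-3.18 ± 0.57), Egf (-3.09 ± 0.59), Hsd3b2 (-3.09 ± 0.59), Ces1e (-2.83 ± 0.51) and Cyp2d26 (-2.73 ± 0.39). Timp2 was at 0.36 ± 0.16 (adjusted p = 0.0796) and Timp3 at -0.09 ± 0.21 (adjusted p = 0.744). With the replicate block, Timp2 passed (adjusted p = 0.0498), as it did with suffixed probe sets left out (0.54, adjusted p = 0.031), and with the mean of its probe sets Timp3 fell by 0.53 (adjusted p = 0.00528). Col1a1 rose by 4.21 ± 0.38, Mmp2 by 2.68 ± 0.37, Tgfb1 by 0.92 ± 0.25 and Acta2 by 1.74 ± 0.30 (-0.42 with its dim other probe set), while Mmp9 (0.23 ± 0.83) and Tnf (-0.08 ± 0.13) did not pass. In all 4692 genes passed, 1969 higher and 2723 lower, with 2940 without TIMP2-/- sham 3, 2605 without TIMP2-/- UUO 1 and 2507 without TIMP2-/- UUO 2.

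By list in TIMP2-/- UUO, all 18 injury markers rose (median 2.11; fry adjusted p = 3.05e-08), as did 19 of 20 macrophage markers (2.63; 7.3e-07), 20 of 22 interstitial matrix genes (2.39; 3.4e-05), 10 of 21 basement membrane genes with 3 falling (0.65; 1.65e-07) and 9 of 14 fibroblast markers (1.66; 0.000297). Of the TGF-β list 11 rose and 1 fell (1.06; 6.73e-05), of the ADAM and ADAMTS genes 7 rose (1.32; 0.00206), and of the matrix metalloproteinases 7 rose and 2 fell (0.29; 0.0429). In the immune lists, 16 chemokines (1.18; 3.11e-05), 15 interferon-induced genes (1.24; 1.18e-06) and 5 complement genes (0.97; 3.99e-05) rose, and of the TNF list 10 rose and 1 fell (0.72; 3.81e-06). Of the cell cycle genes 14 rose and 1 fell (1.68; 3.4e-05), 9 immediate early genes rose (1.77; 7.83e-05), and of the apoptosis genes 7 rose and 3 fell (0.44; 5.9e-05). Of the proximal tubule markers 18 fell and 1 rose (-1.13; 0.00228), 11 loop and distal markers fell (-1.08; 0.00264), 10 fatty acid oxidation genes fell and 2 rose (-0.56; 0.00506), and 16 oxidative phosphorylation genes fell (-0.43; 0.00274). The TIMP family had 1 gene higher (0.14; 0.00317), and of the adipocyte markers 1 rose (median 1.20, fry adjusted p = 0.139; with the replicate block and only the arrays compared, 0.0325). None of these lists passed with camera, the smallest adjusted p being 0.0604. The call of the matrix metalloproteinases was lost without TIMP2-/- sham 1 (0.129), TIMP2-/- sham 2 (0.0869), TIMP2-/- UUO 2 (0.0621) or TIMP2-/- UUO 3 (0.109). Counts adjusted over the list alone were equal except for interstitial matrix (21), basement membrane (11 higher), fibroblasts (10), loop and distal tubule (13), macrophages (20), chemokines (17), TNF (11 higher), interferon (17), apoptosis (8 higher), fatty acid oxidation (11 lower), oxidative phosphorylation (18) and lists given with the other observations.

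UUO against sham in TIMP3-/- asks the same without TIMP3. Postn (periostin, a matrix protein of activated fibroblasts) rose by 5.85 ± 0.97 (limma, adjusted p = 0.000154; near background in sham). Actg2 (a smooth muscle actin) rose by 5.58 ± 0.86 and the collagen cross-linking enzyme gene Lox by 5.23 ± 0.69. Sprr2f (5.38 ± 0.54), Havcr1 (5.38 ± 0.21), Adipoq (5.37 ± 1.21), Hp (5.30 ± 0.82) and Timp1 (5.12 ± 0.52) completed the 8 largest. The largest falls were those of the transporter gene Slc22a7 (-6.54 ± 0.58), Egf (-5.80 ± 0.59), Cyp2d12 (-5.69 ± 0.66), Hpd (-5.20 ± 0.61), Cyp2d26 (-4.92 ± 0.39), Ces1e (-4.87 ± 0.51), Dnase1 (-4.82 ± 0.50) and Gpx6 (-4.78 ± 0.54). Timp2 rose by 1.97 ± 0.16 (adjusted p = 4.5e-07), and Timp3, near background in both groups, was at -0.40 ± 0.21 (adjusted p = 0.1). Lcn2 rose by 4.97 ± 0.34, Col1a1 by 4.99 ± 0.38, Mmp2 by 3.94 ± 0.37, Acta2 by 2.60 ± 0.30 (0.17 with its dim other probe set, adjusted p = 0.432) and Tgfb1 by 0.99 ± 0.25. Mmp9 did not pass (1.43 ± 0.83; without TIMP3-/- UUO 3 it did, at 2.10 with adjusted p = 0.0455), and Tnf fell by 0.40 (-0.40 ± 0.13, adjusted p = 0.0121; 0.0526 without TIMP3-/- UUO 2). In all 8001 genes passed, 3187 higher and 4814 lower; the median of all genes was -0.191, and -0.061 after cyclic loess. Malat1, a nuclear RNA, had intensities of 8637, 26755 and 8189 on the TIMP3-/- UUO arrays and 183 to 5399 on all other arrays.

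By list in TIMP3-/- UUO, all 22 interstitial matrix genes rose (median 3.70; fry adjusted p = 1.49e-06), with 13 of 14 fibroblast markers (2.69; 3.6e-06), 14 basement membrane genes against 2 that fell (0.98; 7.15e-09), 13 TGF-β genes against 2 (1.78; 5.84e-07), 10 of 13 ADAM and ADAMTS genes (1.97; 6.92e-06) and 7 matrix metalloproteinases against 1 (0.96; 0.00087). All 18 injury markers rose (2.74; 8.37e-09), as did all 20 macrophage markers (2.95; 1.53e-07) and all 17 interferon-induced genes (1.49; 5.18e-07). Of the chemokines 18 rose and 1 fell (1.55; 4.32e-06), of the TNF list 11 and 2 (0.83; 4.32e-06), of complement 5 and 1 (1.07; 4.26e-05), of the cell cycle 15 and 1 (1.79; 6.25e-06) and of apoptosis 9 and 4 (0.50; 2.52e-06), and 10 immediate early genes rose (1.57; 1.61e-05). Proximal tubule markers fell in 20 of 21 (-2.33; 4.32e-06), loop and distal markers in 16 of 19 (-1.71; 9.76e-05) and oxidative phosphorylation genes in 20 of 21 (-0.91; 7.01e-06), and of the fatty acid oxidation genes 12 fell and 1 rose (-1.08; 6.92e-06). The TIMP family had 2 genes higher and 1 lower (0.80; 1.28e-05), and 4 of 6 adipocyte markers rose (1.78; 0.0169). The call of the adipocyte list was lost without TIMP3-/- sham 2 (0.0558), TIMP3-/- UUO 1 (0.0907) or TIMP3-/- UUO 2 (0.0707). None of the lists passed with camera, the smallest adjusted p being 0.0612. Counts adjusted over the list alone were equal except for fatty acid oxidation (13 lower).

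The 3 responses to UUO overlapped in more genes than independent lists would. WT and TIMP2-/- had 2732 called genes in common, all in the same direction (1355 higher and 1377 lower, against 330 and 441 for independent lists). WT and TIMP3-/- had 3400, of which 3397 went the same way (1653 higher and 1744 lower, against 534 and 780), and TIMP2-/- and TIMP3-/- had 4361, of which 4360 did (1782 and 2578, against 506 and 1058). All 3 shared 2646 genes, 1285 higher and 1361 lower, against 85 and 171 for independent lists. No array served in more than 1 of these comparisons. Across genes, which are not independent replicates, the log2 changes correlated at 0.811 between WT and TIMP2-/-, 0.786 between WT and TIMP3-/-, and 0.916 between the knockouts.

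TIMP2-/- UUO against WT UUO asks what the loss of TIMP2 changes in the obstructed kidney. Besides Timp2 itself (-2.32 ± 0.16; limma, adjusted p = 1.2e-06), 2 genes passed, both higher in TIMP2-/-. BC018473, a gene named after a cDNA sequence and lying within 20 Mb of Timp2, was higher by 3.68 ± 0.24 (adjusted p = 1.2e-06), with intensities of 264.9 against 20.63, the latter near background, so that the difference is a lower bound, and by 1.96 with the mean of its probe sets. Wdfy1, which encodes an endosomal FYVE-domain protein, was higher by 2.45 ± 0.33 (adjusted p = 0.00778). The call of Wdfy1 was lost without TIMP2-/- UUO 1 (0.0696) or TIMP2-/- UUO 2 (0.0925) and with only the arrays compared (0.278), and over all alternatives its adjusted p ran from 8.71e-06 to 0.278. The count without WT UUO 3 was 11. An unadjusted p under 0.05 was found for 412 genes, against 620 expected by chance among 12393.

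Genes of injury, fibrosis and proteolysis did not differ detectably between obstructed TIMP2-/- and WT kidneys with 3 arrays in each. Havcr1 was at 0.82 ± 0.21 (limma, adjusted p = 0.688), and Lcn2 (0.44 ± 0.34), Col1a1 (-0.79 ± 0.38), Acta2 (-0.39 ± 0.30), Timp1 (-0.51 ± 0.52), Timp3 (-0.26 ± 0.21), Mmp2 (-0.78 ± 0.37), Mmp9 (-0.74 ± 0.83), Tgfb1 (-0.14 ± 0.25) and Tnf (0.13 ± 0.13) each had an adjusted p of 0.999. Only the TIMP family was called, through the deleted Timp2 (0 higher, 1 lower, fry adjusted p = 0.00143, 0.0955 with camera). The other 31 gave 0.525 (apoptosis) to 0.993. Counts adjusted over the list alone were equal except for injury (1 higher, Havcr1).

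TIMP3-/- UUO against WT UUO asks the same for TIMP3. In TIMP3-/- 49 genes differed, 30 higher and 19 lower. Timp3 was lower by 7.04 (-7.04 ± 0.21; limma, adjusted p = 8.48e-12). The largest rises were those of Malat1 (3.72 ± 0.76, adjusted p = 0.0491), Cfap97 (2.11 ± 0.37), the histone demethylase gene Kdm5a (1.87 ± 0.29), Gsap (1.79 ± 0.26, adjusted p = 0.00627), the interferon-induced GTPase gene Mx1 (1.52 ± 0.18, adjusted p = 0.00248), Wdfy3 (1.51 ± 0.19), the transcriptional repressor gene Rest (1.48 ± 0.19, adjusted p = 0.00306) and Map1b (1.39 ± 0.26). The other largest falls were those of Hpd (-3.48 ± 0.61), Slc22a7 (-3.19 ± 0.58), Gnmt (-2.77 ± 0.55), Cyp2d26 (-2.72 ± 0.39, adjusted p = 0.00616), Cyp2d9 (-2.08 ± 0.38), C8g (-1.88 ± 0.36) and Dpys (-1.63 ± 0.33). Hpd, Gnmt and C8g are also liver transcripts, and the 18 hepatocyte markers, high on WT UUO 2, had a median of -2.32 here (fry p without adjustment = 0.0558). Timp3, Gsap, Mx1, Wdfy3, Rest and Cyp2d26 passed whichever array was left out; each of the other named genes lost its call without at least 1 of WT UUO 1, WT UUO 3, TIMP3-/- UUO 1 and TIMP3-/- UUO 2. The count was 1402 without WT UUO 2 and 1462 without TIMP3-/- UUO 3, and all 49 calls remained in both. Without WT UUO 3, TIMP3-/- UUO 1 or TIMP3-/- UUO 2 the count was 10, 13 and 10, and it was 504 without the 3 doubted arrays. With only the arrays compared 1 gene was called.

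Between obstructed TIMP3-/- and WT kidneys, 9 lists passed with fry and none with camera (smallest adjusted p of the 9, 0.175). Fibroblast and myofibroblast markers were higher in TIMP3-/- (median 0.73; fry adjusted p = 0.0379, 0.29 with an estimated correlation), with no single gene called over all genes and 9 of 14 adjusted over the list alone, the smooth muscle myosin gene Myh11 being at 1.90 ± 0.49 (limma, adjusted p = 0.0924). The TGF-β list (median 0.56; 0.0252, and 0.265 with an estimated correlation) had 2 genes higher and 1 lower adjusted over the list alone, with Inhba at 1.19 ± 0.27, Tgfb2 at 1.19 ± 0.29 and Bmp7 at -1.07 ± 0.28. Basement membrane (median 0.15; 0.0114, and 0.175) had none either way, with Nid1 at 0.76 ± 0.21. Interferon-induced genes (median 0.45; 0.0252, and 0.278) had 1 called, Mx1, and 5 over the list alone, and apoptosis (median 0.13; 0.0165, and 0.278) had 1, Casp8 (0.80 ± 0.16, adjusted p = 0.0491), and 4 higher with 1 lower over the list alone. Proximal tubule markers were lower (median -0.76; 0.031, and 0.391), none over all genes and 16 of 21 over the list alone, with the glucose transporter gene Slc5a2 at -1.53 ± 0.33 and Cyp2e1 at -0.72 ± 0.16. Oxidative phosphorylation genes were lower as a list (median -0.38; 0.031, and 0.391), 11 of 21 over the list alone, and EGF receptor ligands and receptors too (median -0.35; 0.0301, and 0.391), where Egf was at -2.66 ± 0.59 (adjusted p = 0.0627; -3.64 and called without WT UUO 2). The TIMP family, through the deleted Timp3, gave 1.21e-06 (0.391 with camera, median 0.08, mean -1.63). Interstitial matrix (median 0.68; 0.225) and macrophages (0.17) did not pass; without WT UUO 2 they did, with adjusted p of 0.0136 and 0.013, and interstitial matrix also without TIMP3-/- UUO 3 (0.0246).

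Of these lists the TIMP family, which rests on the deleted Timp3, kept its call. Each other call was lost without at least 1 array, and with only the arrays compared (adjusted p 0.266 to 0.389). Left out one at a time in the order WT UUO 1, WT UUO 3, TIMP3-/- UUO 1 and TIMP3-/- UUO 2, the adjusted p of the fibroblast list became 0.16, 0.221, 0.208 and 0.106, that of TGF-β 0.0973, 0.15, 0.111 and 0.0989, that of proximal tubule 0.0973, 0.177, 0.111 and 0.112, that of oxidative phosphorylation 0.0973, 0.177, 0.111 and 0.123, and that of the EGF receptor list 0.106, 0.15, 0.111 and 0.106. Interferon was lost without the first 3 (0.0973, 0.15 and 0.111), apoptosis without WT UUO 3 (0.0588) or TIMP3-/- UUO 1 (0.089), and basement membrane without TIMP3-/- UUO 1 (0.089). Without WT UUO 2 the genes called over all genes were 10 interstitial matrix (median 1.19), 7 macrophage (median 0.80), 8 fibroblast (0.0017), 5 basement membrane (0.00168) and 3 interferon-induced genes higher (0.00456), 6 TGF-β genes higher and 1 lower (0.00033), 3 apoptosis genes higher and 1 lower (0.00194), and 17 proximal tubule (0.00168) and 10 oxidative phosphorylation genes lower (0.00173). Without the 3 doubted arrays they were 6 fibroblast (median 1.13; 0.00761), 3 basement membrane (0.00331), 3 interferon-induced (0.00544), 2 TGF-β genes with 1 lower (0.00321), and 8 proximal tubule (0.00772) and 1 oxidative phosphorylation genes lower (0.00925). Macrophages then passed too (0.0156), and interstitial matrix did not (0.0605). Injury markers did not pass (0.324), with Havcr1 at 0.46 ± 0.21 (limma, adjusted p = 0.225) and Lcn2 at -0.04 ± 0.34 (0.959). Col1a1 (0.63 ± 0.38), Acta2 (0.73 ± 0.30), Timp1 (0.38 ± 0.52), Timp2 (0.21 ± 0.16), Mmp2 (0.56 ± 0.37), Mmp9 (0.24 ± 0.83), Tgfb1 (0.02 ± 0.25) and Tnf (-0.12 ± 0.13) had adjusted p from 0.204 to 0.975. Postn had intensities of 9063, 11485 and 331 on the 3 TIMP3-/- UUO arrays, against 999, 3341 and 408 on those of WT UUO.

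TIMP2-/- UUO against TIMP3-/- UUO compares the obstructed knockouts directly. Timp3 was higher by 6.78 ± 0.21 in TIMP2-/- (limma, adjusted p = 1.51e-11) and Timp2 lower by 2.53 (-2.53 ± 0.16). Slc22a7 (4.35 ± 0.58, adjusted p = 0.00237), BC018473 (3.91 ± 0.24, inexact in size because it was near background in TIMP3-/- UUO), Dnase1 (3.10 ± 0.50), Egf (2.71 ± 0.59), Hpd (2.67 ± 0.61), Slc22a19 (2.67 ± 0.40) and Mep1b (2.64 ± 0.44) were the other largest rises. Malat1 (-4.06 ± 0.76), Actg2 (-3.96 ± 0.86), the calponin gene Cnn1 (-3.09 ± 0.73), Dclk1 (-2.81 ± 0.62), Aspn (-2.70 ± 0.69), Lox (-2.54 ± 0.69) and the proteoglycan gene Vcan (-2.51 ± 0.69) were the other largest falls. In all 1001 genes passed, 755 higher and 246 lower in TIMP2-/-. The count depended on single arrays: it was 273, 285 and 26 without TIMP2-/- UUO 1, 2 and 3, and 38, 26 and 3390 without TIMP3-/- UUO 1, 2 and 3, 626 without the 3 doubted arrays, and 19 with only the arrays compared. Timp2, Timp3, BC018473, Slc22a7, Slc22a19 and Mx1 (-1.19 ± 0.18) passed whichever array was left out, and each other named gene lost its call without at least 1 of the TIMP2-/- UUO arrays, TIMP3-/- UUO 1 or TIMP3-/- UUO 2.

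Lists of matrix and its cells were lower in TIMP2-/- UUO than in TIMP3-/- UUO. Of 22 interstitial matrix genes 13 were lower and none higher (median -1.40; fry adjusted p = 0.0163, 0.325 with an estimated correlation), including Col1a1 (-1.41 ± 0.38; limma, adjusted p = 0.0374) and Col3a1 (-0.86 ± 0.22). Of 14 fibroblast markers 7 were lower (median -1.11; 0.00656, and 0.261), including Myh11 (-2.47 ± 0.49), the desmin gene Des (-1.13 ± 0.23) and Acta2 (-1.11 ± 0.30; -0.48 with its dim other probe set, adjusted p = 0.103). Of 16 TGF-β genes 5 were lower and 1 higher (median -0.91; 0.00281, and 0.0781), with Ccn2 at -1.18 ± 0.27 and Bmp7, an antagonist of the pathway, at 1.07 ± 0.28. Of 21 basement membrane genes 2 were lower (median -0.20; 0.00364, and 0.0781), Nid1 at -0.84 ± 0.21 and Lamc1 at -0.70 ± 0.18, and of 13 ADAM and ADAMTS genes 3 (median -0.68; 0.0237, and 0.325), with Adam12 at -1.39 ± 0.35. Mmp2 was lower (-1.35 ± 0.37, adjusted p = 0.0393) and so was Mmp17 (-0.74 ± 0.22), but the list of matrix metalloproteinases did not pass (0.125; 0.0429 without TIMP3-/- UUO 3), nor did macrophages (0.0867; 0.0378 without TIMP3-/- UUO 3 and 0.0309 without the 3 doubted arrays), with Itgam at -1.02 ± 0.31 and Mrc1 at -1.47 ± 0.46. The interstitial matrix call was lost without TIMP3-/- UUO 1 (0.0959) or TIMP3-/- UUO 2 (0.0607), and that of the ADAM genes without TIMP2-/- UUO 2 (0.053), TIMP2-/- UUO 3 (0.0699), TIMP3-/- UUO 1 (0.177) or TIMP3-/- UUO 2 (0.0614). Urothelium markers went the same way without passing (1 of 6 lower, 4 adjusted over the list alone; median -1.20; 0.0975, and 0.0335 without TIMP2-/- UUO 3 and 0.0378 without TIMP3-/- UUO 3), and how much tissue other than kidney each array held was not measured. Actg2 had intensities of 11854, 6668 and 1409 on the TIMP3-/- UUO arrays and 155, 222 and 851 on those of TIMP2-/- UUO, and Malat1 was higher on each TIMP3-/- UUO array (8189 or more) than on any of TIMP2-/- UUO (1058 or less).

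Lists of tubular function and mitochondria were higher in TIMP2-/- UUO than in TIMP3-/- UUO. Of 21 proximal tubule markers 16 were higher and none lower (median 1.05; fry adjusted p = 0.00453, 0.36 with an estimated correlation), including Slc5a2 (1.83 ± 0.33; limma, adjusted p = 0.0117), the gluconeogenic enzyme gene Fbp1 (1.35 ± 0.26) and Cubn (1.31 ± 0.25). Of 21 oxidative phosphorylation genes 12 were higher (median 0.48; 0.00672, and 0.399), such as Cyc1 (0.81 ± 0.20) and Sdhb (0.78, adjusted p = 0.033), and of 16 fatty acid oxidation genes 6 (median 0.43; 0.0228, and 0.461), such as Ppara (1.45 ± 0.24) and Acaa1b (1.28 ± 0.28). Of 9 EGF receptor ligands and receptors 1, Egf, was higher, with a median of 0.28 (0.0109, and 0.414). The TIMP family had 1 deleted gene each way (0.00065, and 0.999). Without the 3 doubted arrays 14 proximal tubule, 6 interstitial matrix and 3 oxidative phosphorylation genes were called. The fatty acid oxidation call was lost without TIMP2-/- UUO 3 (0.0699), TIMP3-/- UUO 1 (0.1) or TIMP3-/- UUO 2 (0.0645), and that of the EGF receptor list without TIMP3-/- UUO 1 (0.0544). Injury markers did not pass (0.432), with Havcr1 at 0.36 ± 0.21 and Lcn2 at 0.48 ± 0.34, nor did interferon-induced genes (0.153; 0.0384 without the 3 doubted arrays), Timp1 (-0.89 ± 0.52), Mmp9 (-0.98 ± 0.83), Tgfb1 (-0.16 ± 0.25) or Tnf (0.26 ± 0.13). Adjusted over the list alone, the counts were larger for interstitial matrix (22 lower), fibroblasts (12 lower), TGF-β (10 lower), ADAM (4 lower), matrix metalloproteinases (4 lower), macrophages (5 lower), proximal tubule (19 higher), oxidative phosphorylation (17 higher), fatty acid oxidation (8 higher) and the EGF receptor list (4 higher), and equal for the basement membrane, injury, interferon and TIMP lists.

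**Figure D4:**
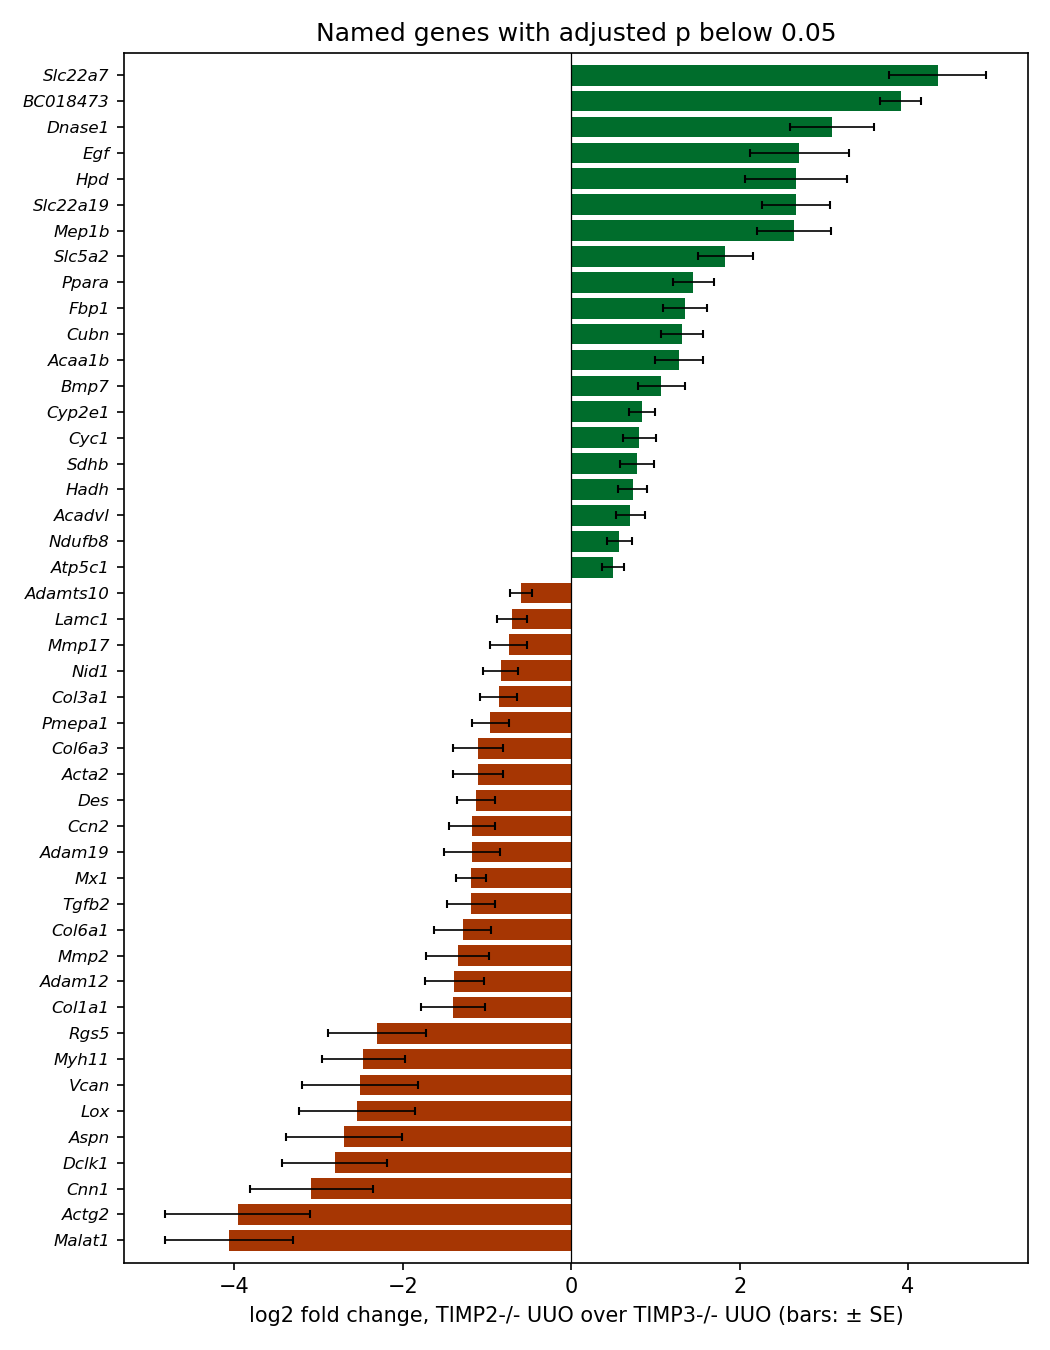
Log2 fold change ± SE of the 46 named genes other than Timp2 and Timp3 that passed in TIMP2-/- UUO against TIMP3-/- UUO, as bars from 0. The 20 genes with green bars were higher in TIMP2-/-, led by Slc22a7, and the 26 with brown bars were higher in TIMP3-/-, led by Malat1 and Actg2.

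TIMP2-/- sham against WT sham asks what the loss of TIMP2 changes without obstruction. Only BC018473 passed, higher by 3.81 ± 0.24 (limma, adjusted p = 9.08e-07). Its intensities were 448.6 against 30.58, the latter near background, so the difference is a lower bound. An unadjusted p under 0.05 was found for 3450 genes, against 620 expected by chance, so 1 call does not mean alike groups. Timp2 was at -0.86 ± 0.16 and Timp3 at -0.79 ± 0.21 (both adjusted p = 0.131). Havcr1 (-0.03 ± 0.21), Lcn2 (0.75 ± 0.34), Timp1 (0.18 ± 0.52), Mmp2 (0.41, adjusted p = 0.444), Mmp9 (0.47 ± 0.83), Tnf (0.21 ± 0.13), Tgfb1 (0.36, adjusted p = 0.318), Col1a1 (0.18 ± 0.38) and Acta2 (0.54 ± 0.30) did not pass. No list passed (smallest fry adjusted p 0.404, the TIMP family, with 2 genes lower adjusted over the list alone). Without TIMP2-/- sham 1 the count was 3. Wdfy1 was at 1.39 ± 0.33 (adjusted p = 0.131), but another of its probe sets was higher by 2.59 (adjusted p = 1.62e-07 over every probe set).

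TIMP3-/- sham against WT sham asks the same for TIMP3. Timp3 was lower by 7.25 (-7.25 ± 0.21; limma, adjusted p = 5.37e-12), and Zbtb7a, a transcriptional repressor gene within 20 Mb of Timp3, was higher by 0.99 ± 0.14 (adjusted p = 0.0293), with intensities of 439.3 against 221.6. The call of Zbtb7a was lost whichever of the 6 arrays was left out (0.116 to 0.262), and over all alternatives its adjusted p ran from 0.000548 to 0.262. Timp2 (0.06 ± 0.16), Havcr1 (0.53 ± 0.21), Lcn2 (0.99 ± 0.34), Timp1 (0.85 ± 0.52), Mmp2 (0.50, adjusted p = 0.558), Mmp9 (0.25 ± 0.83), Tnf (0.28 ± 0.13), Tgfb1 (0.46, adjusted p = 0.492), Col1a1 (0.81 ± 0.38) and Acta2 (0.79 ± 0.30) did not pass. Only the TIMP family was called, through the deleted Timp3 (fry adjusted p = 6.78e-07, 0.729 with camera). Macrophages did not pass (0.426), with 7 genes higher adjusted over the list alone.

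The differences between the UUO responses ask whether genotype changed the response itself, and they have larger errors than the comparisons within UUO. For TIMP2-/- minus WT no gene passed with limma (1185 at an unadjusted p under 0.05, against 620 expected by chance). Timp2 was at -1.46 ± 0.22 (adjusted p = 0.108), and passed without WT sham 2 (-1.63, adjusted p = 0.0152) or WT UUO 3 (-1.57, adjusted p = 0.0407). Havcr1 (0.85 ± 0.29), Mmp2 (-1.20 ± 0.52), Col1a1 (-0.96 ± 0.53), Acta2 (-0.92 ± 0.43) and Timp3 (0.52 ± 0.29) had an adjusted p of 0.518, and Lcn2 (-0.31 ± 0.48), Timp1 (-0.69 ± 0.74), Mmp9 (-1.21 ± 1.18), Tgfb1 (-0.51 ± 0.35) and Tnf (-0.08 ± 0.18) had 0.563 to 0.859. No list passed, the smallest fry adjusted p being 0.586.

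For TIMP3-/- minus WT no gene passed either with limma, with 3312 at an unadjusted p under 0.05. Havcr1 (-0.06 ± 0.29), Lcn2 (-1.02 ± 0.48), Col1a1 (-0.18 ± 0.53), Acta2 (-0.06 ± 0.43), Timp1 (-0.47 ± 0.74), Timp2 (0.15 ± 0.22), Timp3 (0.22 ± 0.29), Mmp2 (0.06 ± 0.52), Mmp9 (0.00 ± 1.18), Tgfb1 (-0.44 ± 0.35) and Tnf (-0.40 ± 0.18) had adjusted p from 0.175 to 0.998. No list passed (smallest fry adjusted p 0.233). The count was 958 without TIMP3-/- UUO 3, 3 without WT UUO 1 and 1 without WT UUO 2. UUO called 8001 genes in TIMP3-/- and 4086 in WT, but a larger count in 1 genotype is not a test of the difference.

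For TIMP2-/- minus TIMP3-/- only Timp2 passed (-1.61 ± 0.22; limma, adjusted p = 0.0346), as it rose in TIMP3-/- and was at 0.36 in TIMP2-/-. Its call was lost without any 1 of the 12 arrays (0.0626 to 0.187) except TIMP3-/- UUO 3 (0.0183), with the mean of its probe sets (0.206) and with suffixed probe sets left out (0.217). With only the arrays compared 30 genes were called. Havcr1 (0.91 ± 0.29), Lcn2 (0.71 ± 0.48), Col1a1 (-0.78 ± 0.53), Acta2 (-0.87 ± 0.43), Timp1 (-0.21 ± 0.74), Timp3 (0.31 ± 0.29), Mmp2 (-1.26 ± 0.52), Mmp9 (-1.20 ± 1.18), Tgfb1 (-0.07 ± 0.35) and Tnf (0.32 ± 0.18) did not pass (adjusted p 0.313 to 0.946). No list passed; the smallest fry adjusted p, 0.0611, was that of proximal tubule markers (16 higher adjusted over the list alone), fatty acid oxidation, TGF-β and basement membrane. Without TIMP3-/- UUO 3 the count was 231, these lists had 0.0291 to 0.038 and the fibroblast list moved from 0.174 to 0.0336, and without the 3 doubted arrays the 4 lists had 0.0389 to 0.0465.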

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

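The difference of responses in this part was a planned comparison, and none of its tests was chosen after the result was seen. The 1 result that stood out by rule was a difference between genotypes under the same operation, tested by the interaction itself: Timp2 responded less to UUO in TIMP2-/- than in TIMP3-/-, by -1.61 on the log2 scale (limma, adjusted p = 0.0346). All 3 TIMP2-/- UUO arrays lay below all 3 TIMP3-/- UUO arrays. The call was lost without any 1 of the 12 arrays (adjusted p = 0.0626 to 0.187) except TIMP3-/- UUO 3 (0.0183). The gene is the one targeted in TIMP2-/-, so this difference is a check of the labels more than a response. The groups held 3 arrays each, and groups of that size were not tested for single outlying arrays.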

How the results depend on the processing

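The settings named as leaving out 2 or 3 arrays and the block with only the arrays compared were chosen after the data were seen; the others were planned. Over all settings, 132 of the counts of genes stayed within 1.5 times the reported one and 83 moved further; of the exact tests of genes near a targeted one 7 stayed, 2 passed and 3 lost the threshold. Single genes kept direction and side in 5409 cases, became weaker in 421, stronger in 215 and reversed in 89, and lists did so in 1933, 198, 77 and 34. Where not said otherwise the cause was not tested. The number of arrays limits every count, and dim genes lie near background. Below, comparisons keep the order WT, TIMP2-/- and TIMP3-/- for UUO.

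Testing every probe set separately, which tests more items, gave 6971, 7922 and 14145 calls for UUO, 11 for TIMP2-/- UUO against WT UUO, 160 for TIMP3-/- UUO against WT UUO, 1597 for TIMP2-/- UUO against TIMP3-/- UUO, 5 and 10 for TIMP2-/- and TIMP3-/- sham, and 0 for TIMP2-/- minus TIMP3-/-. A 2-fold minimum, which only removes calls, left 1588, 1388 and 3096 for UUO, 396 for TIMP2-/- UUO against TIMP3-/- UUO and 1 for TIMP3-/- sham. Array weights, whose estimation stopped before it converged, gave 6245 and 9554 for UUO in WT and TIMP2-/-, 795, 4537 and 5408 for the 3 comparisons within UUO, 2826 and 1517 for sham, and 1132, 5007 and 4019 for the differences; Timp1 was -0.21 in TIMP2-/- sham, Timp2 -0.09 in TIMP3-/- sham, Timp1 0.03 and Lcn2 0.16 in TIMP2-/- minus WT, Timp1 0.88, Mmp9 2.42, Col1a1 0.70 and Acta2 0.78 in TIMP3-/- minus WT, and Tgfb1 0.04 in TIMP2-/- minus TIMP3-/-. With the weights the list p were 0.998 for endothelial and 0.897 for neutrophil markers in WT, 0.409 for urothelium and 0.615 for podocytes in TIMP2-/-, and 0.14 for neutrophils in TIMP3-/-, all with the direction turned.

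Without the 3 doubted arrays the counts were 2441 for UUO in WT, 504 for TIMP3-/- UUO against WT UUO, 626 for TIMP2-/- UUO against TIMP3-/- UUO and 0 for TIMP2-/- minus TIMP3-/-. Directions turned for Timp1 (0.20), Mmp9 (0.37), Tgfb1 (0.01) and the macrophage and metalloproteinase lists (0.984 and 0.984) in TIMP2-/- UUO against WT UUO, Timp2 in TIMP3-/- sham (-0.07), Timp1 in TIMP2-/- minus WT (0.17), Timp1 (0.70), Mmp9 (1.54), Col1a1 (0.34), Acta2 (0.42) and Havcr1 (0.14) in TIMP3-/- minus WT, and neutrophils in TIMP3-/- (0.369). Without the 2 arrays apart on the second component the counts were 9, 22 and 1 for TIMP3-/- UUO against WT UUO, TIMP2-/- UUO against TIMP3-/- UUO and TIMP3-/- sham, and 0 for TIMP2-/- minus TIMP3-/-; Timp2 was -0.07 in TIMP3-/- sham, Mmp9 0.43 and Acta2 0.04 in TIMP3-/- minus WT, and neutrophils 0.754 in TIMP3-/-. With the mean of a gene's probe sets Timp4 was 0.01 in WT, Atp5c1 0.13 in TIMP3-/- UUO against WT UUO, Timp2 -0.02, Col1a1 0.02 and Acta2 0.16 in TIMP3-/- minus WT, urothelium 0.818 in TIMP2-/-, podocytes 0.935 in TIMP3-/-, and the counts 2 for TIMP2-/- sham and 0 for TIMP2-/- minus TIMP3-/-. With suffixed probe sets left out Acta2 was -0.21, -0.42 and 0.37 in WT, TIMP2-/- and TIMP3-/- minus WT, Atp5c1 0.66 in TIMP3-/- UUO against WT UUO and -0.43 in TIMP2-/- UUO against TIMP3-/- UUO, neutrophils 0.99 in WT, podocytes 0.888 in TIMP2-/-, and the counts 1 for TIMP3-/- sham and 0 for TIMP2-/- minus TIMP3-/-. Cyclic loess gave Tgfb1 -0.01 and Lcn2 0.06 in TIMP3-/- UUO against WT UUO, Acta2 0.11 and Havcr1 0.06 in TIMP3-/- minus WT, skeletal muscle 0.735 in WT and neutrophils 0.593 in TIMP3-/-. With only the arrays compared, the counts were 1 for TIMP3-/- UUO against WT UUO, 19 for TIMP2-/- UUO against TIMP3-/- UUO, 1 for TIMP3-/- sham and 30 for TIMP2-/- minus TIMP3-/-, and neutrophils had 0.764 in TIMP2-/-. This setting has fewer degrees of freedom and no longer shares a spread with the other groups. The median SD of a gene was 0.264 in TIMP3-/- UUO, 0.201 in WT UUO and 0.143 in TIMP2-/- sham. A shared spread can thus understate that of the noisier groups. UUO in TIMP2-/- went up from 4692 to 5198 calls, so fewer degrees of freedom are not the whole cause. Leaving out the dimmest 25% gave 0 for TIMP2-/- sham and neutrophils 0.154 in TIMP2-/- and 0.0139 in TIMP3-/-, the variance trend gave 1 for TIMP3-/- sham, and camera turned podocytes in TIMP2-/- (0.895) and neutrophils in TIMP3-/- (0.876). Near Timp2 the exact p in TIMP2-/- UUO was 0.0224 at 5 Mb and 6.6e-05 at an unadjusted p under 0.001, and in TIMP2-/- sham 0.0558 at 50 Mb; near Timp3 in TIMP3-/- sham it was 1 at 5 Mb and 0.193 at an unadjusted p under 0.001.

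With the replicate block, UUO in TIMP2-/- called 4977 genes, with 4602 of the 4692 kept (6904 with only the arrays compared), and TIMP2-/- UUO against WT UUO 3. In these 2 comparisons, where the numbers may pair the arrays, the block changed the calls of Timp2 (0.0498) and of the adipocyte (0.0325 with only the arrays compared), transition regulator (0.0124), lymphocyte, skeletal muscle and sex-linked lists in TIMP2-/-, and no other call among the named genes and the lists discussed. Elsewhere the arrays share only a number: TIMP3-/- UUO against WT UUO had 84 calls and TIMP3-/- sham 1 under the block, with pair correlations of -0.35, 0.21 and 0.64 in the former. Not every array correlated best with its own number there.

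Leaving out 1 array at a time, the counts ranged from 2507 to 5537 for UUO in TIMP2-/-, 2 to 11 for TIMP2-/- UUO against WT UUO, 10 to 1462 for TIMP3-/- UUO against WT UUO, 26 to 3390 for TIMP2-/- UUO against TIMP3-/- UUO, 1 to 3 and 1 to 1 for sham, and 0 to 2, 0 to 958 and 0 to 231 for the differences. Signs turned within these ranges: Tnf -0.05 to 0.05 in WT; Timp3 -0.31 to 0.11 and Mmp9 -0.10 to 0.43 in TIMP2-/-. In TIMP2-/- UUO against WT UUO Timp1 ran from -0.93 to 0.20, Mmp9 -1.32 to 0.37, Tgfb1 -0.23 to 0.01, and the injury, macrophage and metalloproteinase p 0.696 to 0.948, 0.348 to 0.986 and 0.348 to 0.986. In TIMP3-/- UUO against WT UUO Timp1 ran from -0.25 to 1.08, Mmp9 -0.88 to 1.35, Tgfb1 -0.27 to 0.32 and Lcn2 -0.43 to 0.39, and in TIMP2-/- UUO against TIMP3-/- UUO Mmp9 -1.64 to 0.15 and Tgfb1 -0.46 to 0.12. In sham Havcr1 ran from -0.09 to 0.06 (TIMP2-/-) and Timp2 -0.07 to 0.24 (TIMP3-/-). In the differences Timp1 ran from -1.11 to 0.02 (TIMP2-/- minus WT) and, for TIMP3-/- minus WT, Timp2 -0.02 to 0.28, Timp1 -1.10 to 0.23, Mmp2 -0.30 to 0.51, Mmp9 -1.13 to 1.10, Col1a1 -0.60 to 0.28, Acta2 -0.36 to 0.32 and Havcr1 -0.27 to 0.16; for TIMP2-/- minus TIMP3-/-, Timp1 -0.53 to 0.42 and Tgfb1 -0.37 to 0.22. List p ran from 0.402 to 0.929 for neutrophils in WT, 0.464 to 0.946 for urothelium and 0.72 to 0.996 for podocytes in TIMP2-/-, and 0.354 to 0.938 for neutrophils and 0.0895 to 0.91 for lymphocytes in TIMP3-/-.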

Other observations

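In this part the tests on hepatocyte transcripts, on the sham difference, on single probe sets and on genes near the targeted genes were chosen after the results were seen, and so were the lists described here; the adjustment for the difference between arrays within groups and the counts of other splits of the samples were written before. Several gene groups that the comparisons above leave out moved with obstruction. In TIMP3-/- UUO, 4 of 6 urothelium and basal epithelium markers rose (median 1.43; fry adjusted p = 0.0169, 0.399 with an estimated correlation), among them the basal keratin genes Krt14 (3.51 ± 0.57; limma, adjusted p = 0.000122) and Krt5 (2.08 ± 0.47), while none passed in TIMP2-/- (median -0.02, mean 0.23; 0.907) and 2 did in WT (median 0.83; 0.0713, and 0.0238 without WT UUO 3; 1 and a median of 0.32 without WT UUO 2). The call in TIMP3-/- was lost without TIMP3-/- UUO 1 (0.0627) and with the mean of each gene's probe sets (0.0552). Regulators of the epithelial-mesenchymal transition rose in 5 of 7 in TIMP3-/- (median 1.17; 0.000466, and 0.219 with an estimated correlation), with Zeb2 at 2.78 ± 0.45, Snai2 at 1.75 ± 0.38 and Twist1 at 1.42 ± 0.34. In WT 2 of 7 rose (median 0.49; 0.0182, and 0.307 with an estimated correlation; lost without WT sham 1, 0.0759, WT UUO 2, 0.0775, or the 3 doubted arrays, 0.133). In TIMP2-/- 1 of 7 rose (median 0.41; 0.0501, 0.0267 without TIMP2-/- UUO 3, and 0.0124 with the replicate block). All 3 red cell transcripts passed as lower in each genotype (1 in WT without WT UUO 2, 0.00317, or the 3 doubted arrays, 0.00618). Medians were -1.57, -2.54 and -2.82 in WT, TIMP2-/- and TIMP3-/- (fry adjusted p = 0.000436, 2.9e-05 and 3.6e-06, and 0.204, 0.146 and 0.218 with an estimated correlation). In TIMP3-/- Alas2, the erythroid haem synthesis enzyme, was at -2.82 ± 0.28. Slc4a1, an anion exchanger also of collecting duct cells, was at -3.71 ± 0.57. Hba-a1 (-0.61), near background in both groups there, was not readable.

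Endothelial genes split in WT UUO: 6 of 14 rose, such as Pecam1 (0.86 ± 0.19) and Eng (0.79 ± 0.17), and 2 fell (median 0.42, and 0.27 without WT UUO 2; fry adjusted p = 0.17, 0.0382 without WT UUO 1). In TIMP2-/- 4 fell and none rose (median -0.01; 0.558), and in TIMP3-/- 5 rose and 3 fell (median 0.22; 0.296). Without the 3 doubted arrays the list passed in TIMP3-/- (0.0442), and in WT 2 rose and 1 fell (0.636). Lymphocyte and NK markers went both ways in WT, 5 higher, including Cd79b (1.23 ± 0.20) and the granzyme gene Gzma (1.20 ± 0.21), and 2 lower (4 adjusted over the list alone; 0.207); TIMP2-/- had 5 and 2 (0.419; 0.0302 with the replicate block and only the arrays compared) and TIMP3-/- 3 and 4 (0.784; 6 and 0 without the 3 doubted arrays, 0.0948). Of 10 neutrophil markers 2 were higher and 1 lower in WT (median -0.03, mean 0.61; 0.673; none without WT UUO 2), none and 2 in TIMP2-/- (median -0.25, mean 0.18; 0.443), and 3 and 4 in TIMP3-/- (median -0.16, mean 0.59; 0.784), and S100a8 had intensities of 2126 on WT UUO 2 and 1514 on TIMP3-/- UUO 1 but 121 to 399 on the other arrays of these groups. Podocyte markers did not pass in WT (2 of 7 higher; 0.0527, and 0.0251, 0.0228 and 0.0244 without WT sham 2, WT UUO 2 and WT UUO 3), TIMP2-/- (2 higher and 1 lower; 0.926) or TIMP3-/- (3 and 1; 0.184). EGF receptor ligands and receptors fell as a list in WT (2 genes, 1 adjusted over the list alone; 0.0323; 1 without WT UUO 2), TIMP2-/- (2; 0.0209) and TIMP3-/- (4; 9.87e-05), with 0.503, 0.589 and 0.399 as adjusted p with an estimated correlation. The WT call was lost without WT sham 1 (0.113), WT sham 2 (0.104) or WT UUO 1 (0.05), and the TIMP2-/- call without TIMP2-/- sham 3 (0.0671), TIMP2-/- UUO 1 (0.0664) or TIMP2-/- UUO 2 (0.0563). Adrenal cortex markers, all with small changes, fell in TIMP2-/- (5 of 7, 6 adjusted over the list alone; 0.00561, 0.416 with an estimated correlation) and TIMP3-/- (6; 0.00114, and 0.416; 3 without the 3 doubted arrays, 0.012), and in WT 1 fell (0.0762; none without WT UUO 2). Skeletal muscle markers gave 0.262 in WT (1 lower, none adjusted over the list alone), 0.0494 in TIMP2-/- with no gene called (0.589 with an estimated correlation, and 0.0643 with the replicate block; lost without TIMP2-/- sham 1, 2 or 3 or TIMP2-/- UUO 1, at 0.102, 0.0538, 0.122 and 0.21) and 0.0895 in TIMP3-/- (1 higher and 2 lower; 0.0207 without TIMP3-/- sham 1). Of the 4 sex-linked genes, Xist had intensities of 35.4 to 88.6 and Kdm5d of 71.6 to 363.6 over all 18 arrays; the list gave 0.31 in WT, 0.354 in TIMP2-/- (1 higher, none over the list alone; 0.032 with the replicate block and only the arrays compared) and 0.0287 in TIMP3-/- (2 higher and 1 lower; 0.399 with an estimated correlation), the last lost without TIMP3-/- sham 2 (0.111), TIMP3-/- sham 3 (0.0679), TIMP3-/- UUO 2 (0.0788) or the 3 doubted arrays (0.0639).

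The first pattern was the hepatocyte transcripts of WT UUO 2. All 18 hepatocyte markers were higher on that array than on each of the other 17, but the 18 were chosen after such transcripts had been seen there, so the count describes the pattern and does not test its source. An acute-phase response of the kidney itself is argued against by 7 hepatocyte genes outside that response, which were higher by a median of 5.91 (2.06 to 7.79) than on the other WT UUO arrays. A liver sample labelled as kidney is argued against by the proximal tubule score of -2.08, within the -2.39 to -0.67 of the other 8 UUO arrays. Liver tissue carried over with the right kidney stays open, as a hypothesis without a test of its own, and the design gives no biological explanation for 1 array of a group.

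The second pattern was the 30 genes, Malat1, Kdm5a, Rest and Mx1 among them, that were higher in TIMP3-/- UUO than in WT UUO. With a score for the main difference between arrays within groups in the fit (46.5% of the variance within groups), 27 of the 30 kept their call and their median went from 1.08 to 0.96 (SD over the genes 0.43). Of the 19 lower genes, 13 kept theirs. The 30 genes were picked by a small p in the same arrays, which favours genes that vary little within groups. The adjustment could therefore hardly remove their calls, and it does not decide whether that difference is the cause. Liver in WT UUO 2 could raise genes here only by diluting the kidney's transcripts, which is argued against by a median of 1.18 (SD 0.64) without that array, with 26 of the 30 changing by more; this test was put in after its values were seen, in place of a count of calls kept (all 30) that decides little where 1402 genes are called. A genotype difference present without obstruction stays open: 26 of the 30 were also higher in TIMP3-/- sham than in WT sham, but by a median of only 0.27, 8 of them at an unadjusted p under 0.05, while 67.6% of all genes were higher there. An effect of losing TIMP3 on the obstructed kidney is likewise open and was not tested apart from genotype.

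The third pattern was the set of genes beside the targeted ones, where sequence from the strain of the stem cells could remain. In TIMP2-/- UUO against WT UUO, 1 of the 2 called genes other than Timp2 lay within 20 Mb of it (Fisher's exact test, 2-sided p = 0.0533, 0.0711 adjusted over 4 tests), and at an unadjusted p under 0.001 it was 5 of 17 (BC018473, Lsm12, Mettl23, Prkca and Usp36; p = 6.6e-05, 0.000264 adjusted), against 2.7% of all genes, which is consistent with such a flank. A variant under a single probe set of BC018473 cannot be told apart from a change in its RNA, because its other probe set, at 0.23, is dim (mean log2 4.29), whereas for Wdfy1, on another chromosome, another probe set was at 2.46 and argues against it, although the remaining one, of similar brightness (mean log2 7.45), was at 0.86. For Timp3, 4.2% of the 48 other genes called in TIMP3-/- UUO (Upb1 and Zbtb7a) lay within 20 Mb, against 1.92% of all genes (exact p = 0.236; 6 of 139 at an unadjusted p under 0.001, p = 0.0519), so a flank is not the whole cause there. In sham, the 1 gene called besides the targeted one lay within 20 Mb in each knockout (exact p = 0.027 for TIMP2-/- and 0.0192 for TIMP3-/-, both 0.054 adjusted), and at an unadjusted p under 0.001 it was 4 of 49 for TIMP2-/- (p = 0.0428, 0.0692 adjusted; 1 of 49 within 5 Mb, p = 0.426) and 1 of 11 for TIMP3-/- (p = 0.193).

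Other splits of the samples were counted for each comparison, the real one included. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split called 4086, 4692 and 8001 genes for UUO in WT, TIMP2-/- and TIMP3-/-, and the highest other split 0 in each. It called 3 genes for TIMP2-/- UUO against WT UUO (highest other 1), 1001 for TIMP2-/- UUO against TIMP3-/- UUO (highest other 1), and 1 and 2 for the sham comparisons of TIMP2-/- and TIMP3-/- (highest other 0). In the 2 comparisons where the numbers may pair the arrays, 4 of the 10 splits part all 3 pairs, and the others among these called 0. The 1 gene came from a split that parts fewer pairs. For TIMP3-/- UUO against WT UUO, 2 of the 10 splits called at least the real 49, and the other called 2550: WT UUO 1, WT UUO 3 and TIMP3-/- UUO 3 against WT UUO 2, TIMP3-/- UUO 1 and TIMP3-/- UUO 2. That points to a structure of the samples other than genotype, although Timp3 followed the labels on each array. For the differences of responses 100 splits were drawn. All 100 called at least the real 0 for TIMP2-/- minus WT (highest other 1) and for TIMP3-/- minus WT (highest other 4711, with 9 splits above 100), but a real count of 0 is reached by every split, so these 2 counts decide nothing. The 4711 again points to a structure of the samples. For TIMP2-/- minus TIMP3-/- only 1 of 100, the real split with Timp2, called any gene. That gene is the one deleted in TIMP2-/-, which splits that mix the genotypes could hardly call, so the count is not taken to exclude chance.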
